A study of Homo sapiens with 6 samples.

How the data were processed

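Total RNA of 6 samples, 2 from each of the Burkitt lymphoma lines Namalwa, Raji and Ramos, was labelled with biotin and hybridised to Affymetrix U133 Plus arrays, per the labels. The deposited values are log2 intensities that the authors made with RMA, which corrects background, normalises quantiles across arrays and summarises probes per probe set. The design text in the labels names RMA in BRB Array Tools and the processing notes name GCOS and RMA, without versions. The labels' design text describes a filter on varying probe sets, which the deposited table does not carry, since it holds 54675 probe sets. Nothing was normalised again for the main results. Array medians were 4.36 to 4.44 on the log2 scale, and no detection calls were used. Because RMA gives the probes of every array the same distribution, a shift of all RNAs in one direction would not be visible.

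Of the probe sets, 62 were controls, 41091 carried 1 gene symbol, 1801 several and 11721 none in the platform annotation. Symbols were updated through Entrez gene IDs for 41037 probe sets with a RefSeq gene table of assembly GRCh38.p14, used for names only. A gene was represented by its probe set with the highest mean over the 6 arrays, which gave 19775 genes, and 12012 with a mean at or above the median of all non-control probe sets (4.42) were tested. No gene was named from a probe set with several genes. XIST and genes of the Y chromosome were not named. Of EZH2 and the 24 genes named from the group comparison, 11 had over 1 probe set above that level, and for 3 of them (RNF213, LOXL2 and SLC7A11) 1 other probe set moved the opposite way.

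Groups were taken from the labels, with the cell line as the pair. The pairing was checked as the correlation of deviations from the group means: it was 0.861 in Namalwa, 0.950 in Raji and 0.917 in Ramos, each the highest for its line. limma (3.58.1, R 4.3.3) was fitted with the line as a block for miR26a minus empty and with the group as a block for the 3 pairs of lines, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Alternatives tried were no block or a random block, other scalings, other level minimums and probe set rules, an intensity trend and robust prior, no moderation, other thresholds and leaving out each line or array. The closing section gives their effect. Gene lists (27, of which 26 had at least 3 tested genes) were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists, or over lists and pairs of lines. For each line, a list's median change was set among 10000 random lists matched on level in 20 bins. The comparisons, the lists and the rule for named genes were fixed before the data were examined. The rule takes EZH2; up to 12 genes per direction between groups, filled by smallest p among genes that move the same way in 3 lines with a mean change of at least 0.5 log2 where too few pass; up to 8 higher and 4 lower per line; and 2 to 4 members of each list with the largest change. Further members named in the text were chosen after their values were seen.

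The fits were tested on simulated data. For miR26a minus empty, 200 of 12012 genes were changed in each run, by 0.5 or 1 log2. Of these, 31.6% of changes of 0.5 log2 and 98.8% of changes of 1 log2 were recovered, with 5.37% false calls. Between Namalwa and Raji, with 200 genes changed and no other difference between lines, 96.2% of changes of 1 log2 and 100% of 2 log2 were recovered. There 5.97% of calls were false. Recovery depends on how many genes change and by how much, so these shares are not the power of the real comparisons. A simulated list shift of -0.35 was found in 20 of 20 runs with the preset correlation and in 0 of 20 with an estimated one, and 1 of 500 tests of unshifted lists was called; genes were simulated as independent. A test of genes by miR-26a seed sites was not run, because no transcript sequences were used here.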

Results

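RNA levels were measured on Affymetrix U133 Plus arrays in 3 lines of Burkitt lymphoma, an aggressive B-cell lymphoma that carries a MYC translocation: Namalwa, Raji and Ramos. Each line gave 1 array labelled empty and 1 labelled miR26a, so each group held 3 arrays. Per the labels, expression of the microRNA was switched on with doxycycline at 0.5 µg/ml for 72 h. The same dose and time are listed for the empty samples, so the groups do not differ in doxycycline as listed. The study's title places miR-26a between MYC and EZH2, and the comparison of the groups asks which RNAs differ when miR-26a is induced. EZH2 is the methyltransferase of Polycomb repressive complex 2, which methylates histone H3 and keeps genes silent. No source used here says that a line was grown in more than 1 culture per group, so the p-values measure the spread between these samples. The number of arrays limits the precision of every value. Array medians lay between 4.36 and 4.44 on the log2 scale. The Namalwa empty array differed in a sign of RNA quality: its ACTB control probe sets were 3.58 log2 brighter at the 3′ than at the 5′ end, against 1.80 to 1.98 on the other 5 arrays. Its GAPDH difference was smaller, at 0.31 against 0.10 to 0.16. The mean of the 18S control probe sets was 6.68 on the Namalwa empty array and 8.99 on the Ramos empty array, against 7.49 to 7.72 on the rest.

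EZH2 RNA was lower in the miR26a array of each line. Its log2 level was 9.14 ± 0.98 (SD, n = 3) in the empty group and 8.58 ± 0.77 (SD, n = 3) in the miR26a group. The change was -0.76 in Namalwa, -0.31 in Raji and -0.61 in Ramos, so that 58.9%, 80.5% and 65.7% of the empty level was left. The mean paired change was -0.56 (SE 0.12, 95% interval -0.82 to -0.30), a 1.48-fold difference, and EZH2 ranked 87 by p among 12012 genes. Adjusted over all genes it did not pass (limma adjusted p = 0.106). A two-sided exact sign-flip test over the 3 pairs gave p = 0.25, the smallest p that 3 pairs allow. It passed with an intensity trend and robust prior (adjusted p = 0.0406) and without Raji (adjusted p = 0.0193), and over 14 alternatives the adjusted p ran from 0.0193 to 1.00. Among the 11 subunits of the complex on the fixed list, EZH2 alone passed when adjusted over the list alone (limma adjusted p = 0.00867). PHF19, a subunit that recruits the complex to chromatin, was at -0.28, and SUZ12 and EED, core subunits, were at -0.19 and -0.12. The list as a whole did not pass (camera adjusted p = 0.276, and adjusted p = 0.657 with an estimated correlation).

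**Figure D1:**
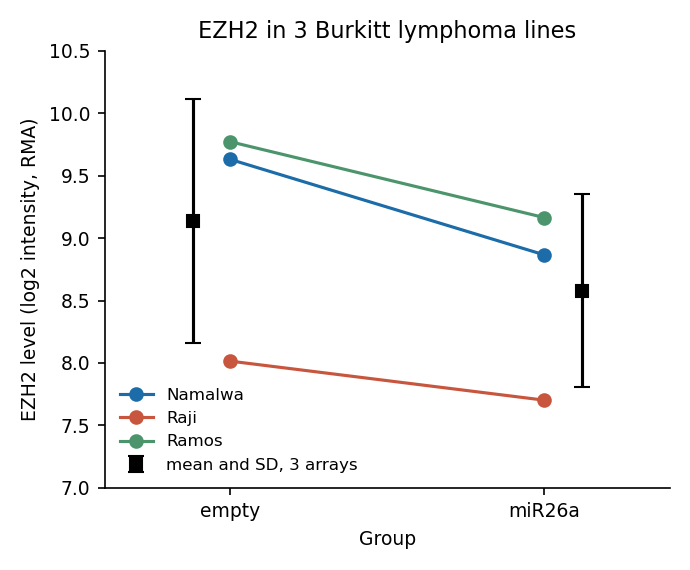
EZH2 level (log2 intensity) in each array, with a line joining the empty and miR26a arrays of 1 cell line. Black squares and bars give the mean and SD of 3 arrays; the level is lower with miR26a in all 3 lines, with changes from -0.76 to -0.31.

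Genes of the cell division cycle were lower with miR26a in Namalwa, Raji and Ramos alike. Of 38 tested genes of G1/S and DNA replication, 32 were lower in all 3 lines and 26 fell when adjusted over the list alone, while 0 passed over all genes. The median change of the list was -0.35 (camera adjusted p = 1.92e-21, and adjusted p = 0.196 with an estimated correlation). CDC6, which loads the replicative helicase, changed by -0.73 (SE 0.11), the chromatin assembly subunit CHAF1A by -0.70 (SE 0.12), the licensing factor CDT1 by -0.61 (SE 0.10) and cyclin E2 (CCNE2) by -0.65 (SE 0.10). Of 38 tested genes of G2/M and mitosis, 33 were lower in all 3 lines and 28 fell when adjusted over the list alone. The median was -0.38 (camera adjusted p = 2.83e-22, and adjusted p = 0.320 with an estimated correlation), with line medians of -0.33, -0.37 and -0.37 in Namalwa, Raji and Ramos. DLGAP5 and KIF2C, which act on spindle microtubules, changed by -0.56 and -0.55, the proliferation marker MKI67 by -0.54 and the checkpoint kinase BUB1 by -0.54. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.47 when adjusted over its list alone (limma adjusted p = 0.00718), and it was 1 of 7 tested inhibitors and pocket proteins to pass. Among 21 tested p53 target genes, 4 rose and 1 fell when adjusted over the list alone: ZMAT3 by 0.48, CDKN1A by 0.47, TP53I3 by 0.40 and SESN1 by 0.38, against -0.39 for PLK3. That list did not pass as a whole (camera adjusted p = 0.217).

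Genes that published work names as miR-26a targets were also lower. Of 48 tested, 23 were lower and 0 higher in all 3 lines, and 13 fell when adjusted over the list alone. The median was -0.15 (camera adjusted p = 2.04e-07, and adjusted p = 0.657 with an estimated correlation). SLC7A11, the cystine importer, changed by -0.74, the pseudokinase STRADB by -0.72, the lysyl oxidase LOXL2 by -0.67, the Mediator kinase CDK8 by -0.63 and the chromatin protein HMGA1 by -0.51. TET3 and TET1, which oxidise methylcytosine, were at -0.48 and -0.42. LOXL2 lay below the level minimum of 4.42 in both arrays of Namalwa and of Ramos, and TET1 in both arrays of Raji, so their mean changes include signals near background. The other 35 members did not pass, among them SMAD4 at -0.07. Of the genes that host the miR-26 copies, CTDSP2 was at -0.17 and CTDSP1 at -0.09, and CTDSPL lay below the level minimum.

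Genes of amino acid supply and the integrated stress response were lower too. Of 27 tested, 17 were lower in all 3 lines and 10 fell when adjusted over the list alone (median -0.22, camera adjusted p = 2.04e-07, and adjusted p = 0.454 with an estimated correlation). Besides SLC7A11 they included the serine synthesis enzyme PSAT1 at -0.58, asparagine synthetase (ASNS) at -0.48 and the amino acid carrier SLC7A5 at -0.42. Sterol and fatty acid synthesis genes had a median of -0.11 over 21 genes (camera adjusted p = 0.00397, and adjusted p = 0.454 with an estimated correlation). MSMO1, a demethylase of cholesterol synthesis, fell by 0.73 and was the only 1 of them to pass when adjusted over the list alone, and HMGCS1 was at -0.38.

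Interferon-stimulated genes were higher with miR26a. Of 23 tested, 15 were higher in all 3 lines and 8 rose when adjusted over the list alone (median 0.24, mean 0.35, camera adjusted p = 4.82e-10, and adjusted p = 0.591 with an estimated correlation). IFIT1 and IFIT2, which bind foreign RNA, rose by 1.25 (SE 0.27) and 1.23 (SE 0.16), the transcription factor IRF9 by 0.69 and the ubiquitin-like modifier ISG15 by 0.62. IFIT1 was at 1.41 in Namalwa and 2.10 in Raji but at 0.24 in Ramos. Its mean level in the empty group was 4.34, below the level minimum of 4.42, so these are differences from a signal near background and no exact sizes.

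Antigen presentation and ribosomal protein genes were higher on average with miR26a, with the highest medians in Namalwa. The median change of 11 MHC class II genes was 0.50 in Namalwa, -0.27 in Raji and 0.40 in Ramos, and 0.22 over the lines (camera adjusted p = 9.66e-04, and adjusted p = 0.657 with an estimated correlation). HLA-DQA1 alone rose there when adjusted over the list alone, by 0.87, with both Raji arrays below the level minimum of 4.42, and HLA-DRA was at 0.34. The 14 MHC class I presentation genes had a median of 0.16 (camera adjusted p = 0.0247, and adjusted p = 0.657 with an estimated correlation), with line medians of 0.34 in Namalwa, 0.03 in Raji and 0.07 in Ramos and HLA-E at 0.37. The 28 ribosomal protein genes had a median of 0.08 (camera adjusted p = 0.00987, and adjusted p = 0.657 with an estimated correlation), with line medians of 0.17, 0.01 and 0.08 and RPS9 at 0.33. All 3 calls were lost without Namalwa, whose empty array had the ACTB difference of 3.58 log2. Without Namalwa, the adjusted p was 0.380 for MHC class II, 0.587 for class I and 0.264 for the ribosomal genes, within ranges of 1.79e-10 to 0.657, 6.46e-06 to 0.657 and 1.47e-04 to 0.657 over 13 alternatives each.

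**Figure D2:**
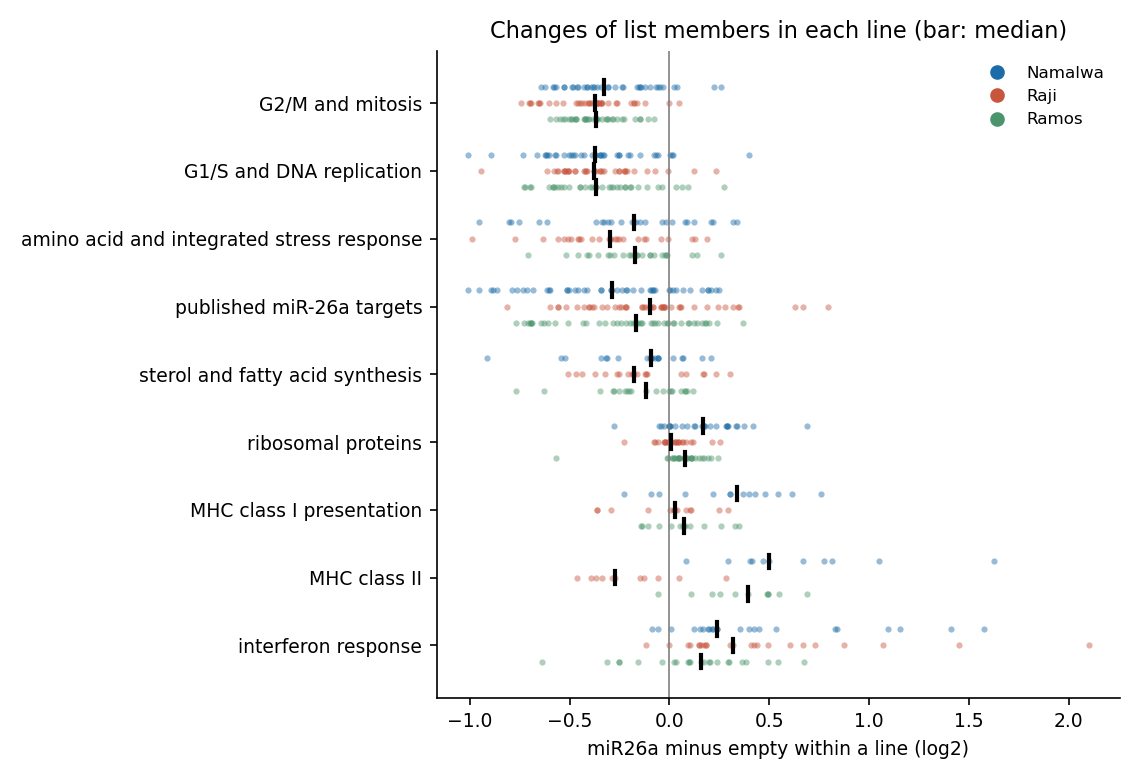
Change of each list member (miR26a minus empty, log2) in each line, for the 9 lists that camera called with its preset correlation; bars mark the median per line. The cell cycle lists lie left of 0 in every line, with G2/M medians from -0.33 to -0.37, and MHC class II lies right of 0 in Namalwa and Ramos and left of it in Raji.

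Of the 26 tested lists, 9 passed with camera's preset correlation, 5 lower and 4 higher, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.196. The run with an estimated correlation cannot decide this: it found a simulated shift of -0.35 in 0 of 20 runs, with genes independent. G1/S lost its call although its estimated correlation was -0.018, below the preset 0.01. Sterol synthesis was also below the preset (-0.048). The other called lists were above it: amino acid 0.052, G2/M 0.069, published targets 0.175, ribosomal 0.184, MHC class I 0.234, interferon 0.281 and MHC class II 0.813. For those lists the preset p-values may be too small. False calls of the preset run were checked only with genes simulated as independent. The rotation test fry passed 2 lists, G1/S (adjusted p = 0.0169) and sterol synthesis (adjusted p = 0.0216). MYC and the genes it induces did not pass (median -0.07, camera adjusted p = 0.116), and MYC itself was at 0.08. Germinal centre B-cell genes did not pass (adjusted p = 0.665), although MYBL1, a transcription factor of germinal centre B cells, fell by 0.61 when adjusted over the list alone. BID, a death agonist of the BCL2 family, fell by 0.49 on that basis, in a list that did not pass (adjusted p = 0.852). Calls of single genes adjusted over a list alone were not corrected for the number of lists. Markers of T and NK cells, monocytes, red cells and fibroblasts did not pass either (adjusted p from 0.665 to 0.960). The same held for Polycomb repressive complex 1 (adjusted p = 0.813), NF-kB and EBV latency III (0.272), plasma cell genes and hypoxia (0.665 each), TGF-beta (0.713), and small RNA machinery and immediate early genes (0.877 each).

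No single gene passed over all 12012 genes tested with limma, where the smallest adjusted p was 0.073. At an unadjusted p under 0.05 there were 1548 genes, 668 higher and 880 lower, against 601 expected on average by chance. Other splits of the arrays into 3 and 3 gave 208 to 998, so the excess is not measured precisely. At an adjusted p under 0.1 there were 79, 29 higher and 50 lower. With no moderation of the spread 0 genes passed, with an intensity trend and robust prior 102 and with the level minimum at the 75th percentile 50. Without Raji 203 genes passed the threshold of 0.05, without Ramos 23 and without Namalwa 0. In 35.1% of the genes the change had the same sign in all 3 lines, against 25% for independent signs. The changes correlated across genes at r = 0.347 between Namalwa and Ramos, 0.194 between Raji and Ramos and 0.144 between Namalwa and Raji; genes are not independent replicates.

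The genes with the smallest p that moved the same way in all 3 lines, with a mean change of at least 0.5 log2, are given here, none past the threshold. On the higher side, the core histone gene H2BC12 was at 0.88 (SE 0.11), the calcium-binding protein S100A4 at 0.87 (SE 0.11) and IFIT2 at 1.23 (SE 0.16). The histone genes H2AC6 and H2BC12L were at 0.91 (SE 0.14) and 0.73 (SE 0.12), the interferon-induced RNF213 at 0.81, the thioredoxin inhibitor TXNIP at 0.61, the laminin chain LAMC1 at 0.64 and the bacterial lipopeptide receptor TLR1 at 0.58. ZNF573, TNFAIP8L2 and LINC00869 were at 0.63, 0.59 and 0.75. On the lower side were POLR3G, a subunit of RNA polymerase III, at -0.84 (SE 0.12), the WNT pathway protein FRAT2 at -0.74 (SE 0.10), the kinesin KIF21B at -0.75, the exonuclease EXO1 at -0.66, the repair polymerase POLQ at -0.64, the formin DIAPH3 at -0.69 and C1orf216 at -0.64. The miR26a arrays of Namalwa and Ramos lay below the level minimum of 4.42 for C1orf216. All had a limma adjusted p of 0.073.

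The lines differed from each other far more than the groups did. Namalwa and Ramos were close to each other and Raji stood apart. Arrays of the same line correlated at 0.9918 to 0.9944, Namalwa with Ramos at 0.9833 to 0.9856, Namalwa with Raji at 0.9449 to 0.9508 and Raji with Ramos at 0.9415 to 0.9455. Of 12012 genes, 5543 differed between Namalwa and Raji (limma, 2805 higher and 2738 lower in Namalwa), 6068 between Raji and Ramos (3133 higher and 2935 lower in Raji) and 1761 between Namalwa and Ramos (972 higher and 789 lower in Namalwa). With a difference of at least 2-fold as well, the counts were 1683, 1868 and 340. Leaving out 1 Namalwa or Ramos array left 870 to 983 genes between those lines: 936 without the Namalwa empty array, 983 without its miR26a array, 870 without the Ramos empty array and 957 without its miR26a array.

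**Figure D3:**
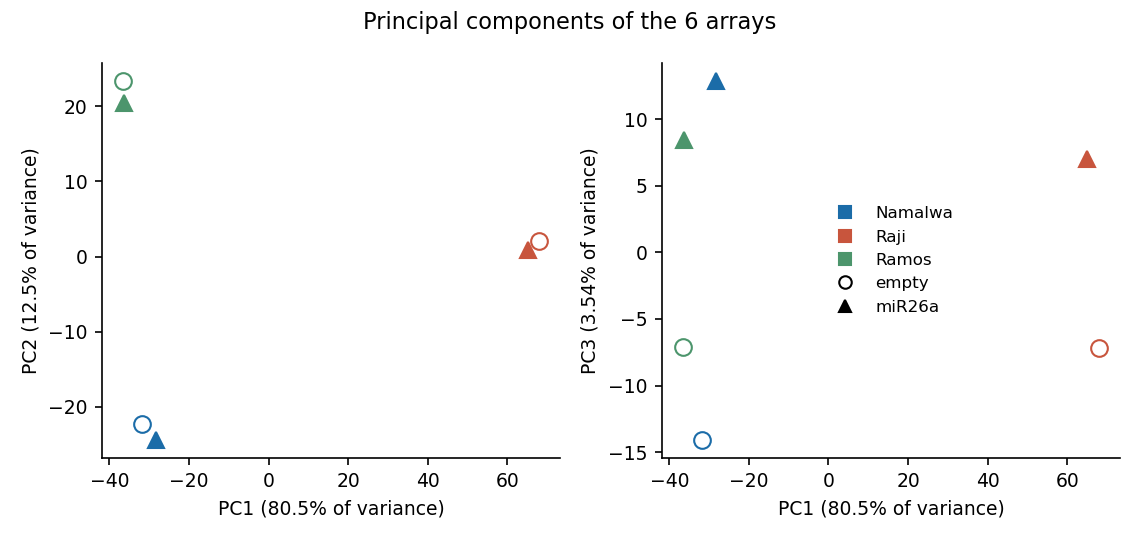
Scores of the 6 arrays on the first 3 principal components of the 12012 tested genes, by line (colour) and group (open circle, empty; triangle, miR26a). PC1 (80.5% of variance) parts Raji from the other lines, PC2 (12.5%) parts Namalwa from Ramos and PC3 (3.54%) parts the groups in every line.

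Raji was set apart by 2108 genes higher and 2230 lower than in both other lines. For 22 of the 35 genes named here by line, the lower level lay below the level minimum of 4.42, so that those ratios compare signals near background and are no exact folds. RAB27B, a small GTPase of secretion, had a mean log2 level of 10.7 in Raji against 3.57 in Namalwa and 3.26 in Ramos. The matricellular protein SPARCL1, the Fc receptor-like FCRL3 and the fungal glucan receptor CLEC7A were at least 119-fold, 49.4-fold and 41.6-fold higher in Raji than in either other line. AK4, SPINK2, LINC01857 and TRIM9 followed with 30.7-fold, 29.6-fold, 25.6-fold and 25.1-fold. HMGN3, a nucleosome-binding protein, was at 2.70 in Raji against 11.5 in Namalwa and 11.6 in Ramos (adjusted p = 6.75e-10 for Namalwa and Raji), and CRNDE, the B-cell surface glycoprotein CD24 and the G protein subunit GNB4 were lower by at least 181-fold, 109-fold and 102-fold. Namalwa had 404 genes higher and 299 lower than both other lines. The AKT coactivator TCL1B was at least 14.6-fold higher there, CMAHP 6.35-fold, the surface receptor SLAMF7 5.46-fold and the cytidine deaminase APOBEC3B 4.86-fold. The calcium channel subunit CACNA1A, PLEKHO1 and HCP5 followed with 4.61-fold, 4.32-fold and 3.98-fold, and the Fc receptor chain FCER1G had a mean level of 7.15 (SD 0.88 between the 2 arrays) against 4.89 in Raji and 5.15 in Ramos. The retrotransposon-derived PEG10 was at 2.37 in Namalwa, 6.92 in Raji and 9.35 in Ramos, and NMU, MIR99AHG and SGCE were lower by at least 15.1-fold, 14.7-fold and 10.4-fold. Ramos had 459 genes higher and 560 lower. The protease inhibitor CSTA was at least 48.8-fold higher in Ramos, TEX30 15.2-fold, LAMP5 14.2-fold and the collagen prolyl hydroxylase P4HA2 7.16-fold, with MCTP1, PCDHGA4, TMTC2 and PEG10 at 6.54-fold, 6.12-fold, 5.54-fold and 5.40-fold. The death inhibitor BCL2A1 was lower in Ramos by at least 6.91-fold, CMTM4 by 5.98-fold, the protease CTSH by 5.42-fold and CD99 by 5.36-fold.

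Raji also had higher levels of genes driven by NF-kB and by the EBV latency III program. Of 30 tested, 19 were higher in Raji than in Namalwa and 22 than in Ramos (camera adjusted p = 1.84e-04 and 1.46e-05, and adjusted p = 0.865 with an estimated correlation in both). FAS, a death receptor, was 14.0-fold higher in Raji than in Namalwa, the cytokine subunit EBI3 12.4-fold and the activation marker CD83 3.96-fold. IRF4 and CCL4 went the other way, with Namalwa minus Raji differences of 2.16 and 2.31. Namalwa exceeded Ramos on the same list, with 9 genes higher and 1 lower (camera adjusted p = 0.00797, and adjusted p = 0.888 with an estimated correlation).

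Sterol synthesis genes were higher in Raji, 15 of 21 against Namalwa and 18 of 21 against Ramos (camera adjusted p = 3.79e-05 and 3.81e-06, and adjusted p = 0.865 with an estimated correlation in both), with DHCR7 4.69-fold above Namalwa. They were higher in Namalwa than in Ramos for 6 of 21 (adjusted p = 0.0101, and adjusted p = 0.865 with an estimated correlation). MHC class II genes were higher in Raji for 9 of 11 against Namalwa and 10 of 11 against Ramos (adjusted p = 0.0191 and 0.0101, and adjusted p = 0.888 with an estimated correlation in both), while HLA-DQA1 was lower in Raji by its brightest probe set (mean levels 7.84 in Namalwa, 3.63 in Raji and 6.76 in Ramos) and higher by another (3.69, 9.99 and 3.79). The call against Namalwa was lost without the Namalwa empty array (adjusted p = 0.0721) and without the Raji empty array (0.0825). Small RNA machinery genes were lower in Raji, 9 of 13 against Namalwa and 8 of 13 against Ramos (adjusted p = 0.0118 and 0.0402, and adjusted p = 0.888 with an estimated correlation in both). LIN28B, which blocks let-7 maturation, differed 15.9-fold between Namalwa and Raji and DICER1, which cuts microRNA precursors, 4.10-fold. SMAD1, a mediator of BMP signals, was at 3.99 in Raji, below the level minimum, against 8.66 in Namalwa, on a TGF-beta and SMAD list lower in Raji than in both others (adjusted p = 0.0126 and 0.0191, and adjusted p = 0.888 with an estimated correlation in both). Without the Raji empty array that call against Ramos was lost (adjusted p = 0.0569).

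The lists of MYC-induced and of amino acid genes were called higher in Ramos than in both others with camera's preset correlation and not with an estimated one (adjusted p = 0.865 against Namalwa and 0.888 against Raji for each list). Of 38 MYC-induced genes, 5 were lower and 0 higher in Namalwa than in Ramos, and 17 lower and 4 higher in Raji than in Ramos. Of 27 amino acid genes, 11 were lower and 1 higher in Namalwa, and 14 lower and 3 higher in Raji. MYC itself was 2.21-fold higher in Ramos than in Raji (adjusted p = 8.62e-05), and the translation repressor EIF4EBP1 14.4-fold. The MYC list was lower in Namalwa than in Ramos (median -0.30, camera adjusted p = 8.93e-06, and adjusted p = 0.865 with an estimated correlation) and lower in Raji than in Ramos (median -0.24, adjusted p = 0.0408, and adjusted p = 0.888 with an estimated correlation). The amino acid list had medians of -0.44 and -0.36 in the same comparisons (adjusted p = 8.00e-07 and 0.0188, and adjusted p = 0.865 and 0.888 with an estimated correlation), with ATF5, a transcription factor of the stress response, 4.95-fold higher in Ramos than in Raji. Against Raji, the MYC call was lost without the Raji miR26a array (adjusted p = 0.131) or either Ramos array (0.0635 and 0.161), and the amino acid call without the Raji miR26a array (0.114) or the Ramos miR26a array (0.0506). EZH2 was 2.62-fold lower in Raji than in Namalwa (adjusted p = 3.78e-05) and did not pass between Namalwa and Ramos (log2 difference -0.22, SE 0.14, adjusted p = 0.351).

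**Figure D4:**
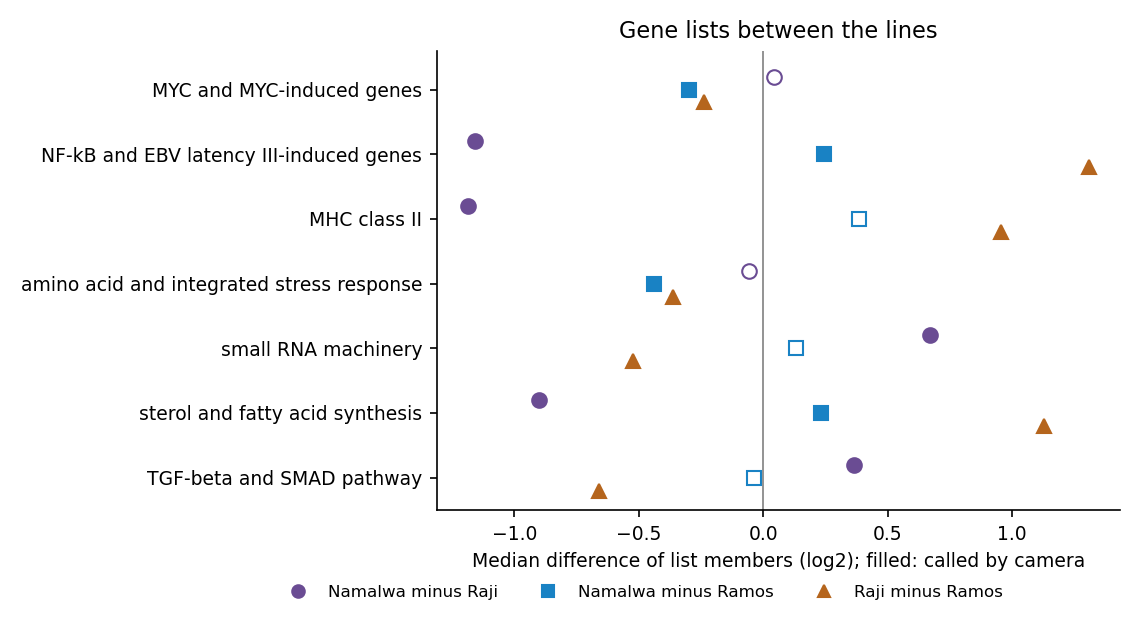
Median difference between lines (log2) of the members of 7 lists, for each pair of lines; filled symbols mark calls by camera with its preset correlation. Raji lies highest for the NF-kB and sterol lists, with medians 1.31 and 1.13 above Ramos.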

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

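The tests in this part were chosen after the result was seen. The MHC class II genes stood out because the median change had opposite signs between lines, at 0.50 in Namalwa, -0.27 in Raji and 0.40 in Ramos; the difference was not tested. Centring each array on its median gave 0.49, -0.24 and 0.37, and quantile normalisation 0.48, -0.17 and 0.37. RNA quality of the Namalwa empty array may have added to the Namalwa value, but cannot account for the Ramos value, since Ramos does not use that array. The Ramos median lay at percentile 100 of the random lists, with Raji at 0.04. These percentiles decide little, because random lists draw genes independently, while the list's estimated correlation was 0.813. The Ramos empty array itself stood apart in the 18S control, with a mean of 8.99 against 7.49 on the Ramos miR26a array. Chance in single arrays stays open, because there was 1 pair of arrays per line, and so does a difference in biology between the lines.

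A probe set outside the tests was 1.46 log2 (2.75-fold) higher with miR26a on average, at 1.12 in Namalwa, 1.63 in Raji and 1.64 in Ramos. The platform annotation assigns it to 10 genes of clustered histone H3, so no single gene can be named. H3C8, 1 of the 10, also has a probe set of its own, which did not pass and was at 0.13 in Namalwa, -0.33 in Raji and -0.05 in Ramos (mean -0.08). The search covered the 13584 probe sets that were controls or carried several gene symbols or none. Untested probe sets with 1 gene symbol were not searched, and probe sets lower with miR26a were not looked for. Among the 13584, the H3 probe set of 10 genes was the only 1 with a mean at or above the level minimum in which every miR26a array exceeded its empty array and the mean change was at least 1 log2.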

How the results depend on the processing

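The alternative that averages Namalwa and Ramos as 1 pair, the target list without cell cycle members and the line lists without each array were chosen after the data were seen. Of the named genes, list calls and line differences, 0 reversed. For named genes the rule largely fixed this beforehand. Between groups they were chosen to move the same way in 3 lines, and between lines for the largest differences. The number of genes changed with miR-26a was 0 with limma, and 50 with the level minimum at the 75th percentile, 102 with an intensity trend and robust prior, 79 at an adjusted p under 0.1, 1 with Namalwa and Ramos averaged, and 0 to 203 without 1 line. It stayed at 0 without moderation, with the line as a random block and with no line block (no replicate block), where EZH2 had the same change of -0.56 (adjusted p = 1.00). EZH2 passed with an intensity trend and robust prior (-0.56, adjusted p = 0.0406) and without 1 line ranged from -0.69 to -0.46. Gene lists passing with miR-26a numbered 9, but 0 with an estimated correlation, 2 with fry, 6 without the block (the MHC class I and II and sterol lists were lost) and 6 to 10 without 1 line. The ribosomal list was lost with quantile normalisation again and among the more variable probe sets (adjusted p = 0.146 and 0.264), and the PRC2 list passed with every probe set or the mean of a gene's probe sets (0.0262 and 0.0380). The share of genes with 1 sign in all 3 lines was 31.5% with no level minimum, 38.8% at the 75th percentile, 36.8% among the more variable probe sets and 37.0% with the mean of probe sets; with 2 lines it was 53.7% to 60.4%, against 50% for independent signs. Between lines, every probe set on its own gave 9482 for Namalwa and Raji, 2781 for Namalwa and Ramos and 10516 for Raji and Ramos, and at least 2-fold as well gave 1683, 340 and 1868. Namalwa and Ramos gave 870 to 2430 without 1 array. The 2430 came when 1 of the Raji arrays, whichever, was left out, and equals the count from the arrays of the 2 lines alone, since a lone array has no residual; where a compared line kept 1 array, it was assumed to vary like the others. List calls between lines numbered 16, but 0 with an estimated correlation, and 15 to 17 without 1 array. The counts with every probe set test more features; the cause of the other shifts was not tested. Named genes between lines, chosen for their large differences, kept their call in 1151 of 1151 tests. Those named between groups had no call to lose. They gained one in 98 of 375, where 24 gains came from the threshold of 0.1 itself, which all of them met beforehand. For lists, camera was run with an intensity trend but no robust prior, and the random block through cameraPR on the t statistics. The seed-site test and its 8mer version were not run. No detection calls were used, so signal over background sets no stated limit.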

Other observations

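The tests of RNA quality, of scaling by random lists, of the Namalwa and Ramos arrays and of the histone genes were chosen after the results were seen; the target list without cell cycle members was added after the data were seen but before its own result was. Core histone genes of the clusters had a median above 0 with miR26a: of 14 with their own probe set above the level minimum, 6 were higher and 0 lower in all 3 lines, with a median of 0.17, and 0.17 or 0.16 after centring or quantile normalisation. H2AC6 and H2BC12 led with 0.91 and 0.88, and H2BC9 and H2BC6 were at 0.55 and 0.50. Without H2AC6 and H2BC12, which prompted the test, the other 12 had a median of 0.14, with 4 higher in all 3 lines and 4 with a mean below 0 (camera p = 0.00365, and p = 0.223 with an estimated correlation). The medians of all 14 were 0.44 in Namalwa, 0.14 in Raji and 0.12 in Ramos.

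B-cell identity genes differed widely between lines in both directions, and their list was not called (adjusted p of 0.562 for Namalwa and Raji, 0.768 for Namalwa and Ramos and 0.604 for Raji and Ramos). MS4A1, which encodes CD20, was 5.41-fold higher in Raji than in Namalwa and 26.3-fold higher than in Ramos. TCL1A was 9.47-fold lower in Raji than in Namalwa, BACH2 was at 4.35 in Raji, below the level minimum, against 8.01 in Namalwa, and SERPINA9, a germinal centre marker, was 9.60-fold higher in Raji than in Namalwa. These genes were chosen after their values were seen.

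The cell cycle lists were called lower and the interferon list higher with miR26a at camera's preset correlation, but not with an estimated one (adjusted p = 0.196 for G1/S, 0.320 for G2/M and 0.591 for interferon). The run with an estimated correlation found a simulated G2/M shift of -0.35 in 0 of 20 runs, so it decides little here. RNA quality of the Namalwa empty array is not the whole of either shift: in Raji and Ramos, which do not use it, the G2/M median lay at percentile 0 of random lists and the interferon median at percentile 99.7 or above. Random lists draw genes independently, while the estimated correlation was 0.0686 for G2/M and 0.281 for interferon. These percentiles may therefore overstate how rare the shifts are. The Ramos empty array also stood apart in the 18S control, at 8.99 against 7.49 on the Ramos miR26a array. Centring each array left the G2/M median at -0.38 but decides nothing, since array medians within a line differed by at most 0.0271; a scaling error alike for genes of like level is argued against by the random lists, matched on level, where the G2/M median lay at percentile 0 and the interferon median at 99.7 or above in all 3 lines. An effect of the microRNA stays open, and the groups could also differ in how the cultures were grown, which was not tested. The only control group is labelled empty, and no array is labelled with another microRNA. An effect particular to miR-26a therefore cannot be told apart from one of expressing any microRNA. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. As many lists were called in 1 split, the real one. It gave 9 lists, against a highest other of 8, and 4 to 7 in the 3 other splits that part every pair. As many genes with an unadjusted p under 0.05 were found in 1 (1548, highest other 998). The 3 other splits that part every pair gave 208 to 524 such genes. As many genes with an adjusted p under 0.05 were found in 10 (0 genes in each). The highest others, 8 lists and 998 genes, came from splits that part only the Namalwa pair. Those splits hold that line's own change and are no reference for chance.

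Without the 4 members on the cell cycle lists, the published targets kept a shift at camera's preset correlation (camera p = 1.69e-06 over 44 genes). Their mean was -0.19 and their median -0.10, and camera gave p = 0.168 with an estimated correlation. Only members on the cell cycle lists were removed, so other genes that fall along with the cell cycle may remain among the 44. The test therefore cannot separate a shift of targets from a wider fall of genes linked to cell division.

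Namalwa and Ramos, lines of different patients, gave arrays close to each other. Of 20 HLA-DQ and HLA-DR probe sets, 0% differed at least 4-fold between them, against 40% between Raji and either, and IGLC1, an immunoglobulin light chain gene, was at 12.4 in Namalwa and 12.8 in Ramos but 9.15 in Raji. A common origin of the 2 cultures is a candidate explanation for this, and like HLA types by chance stay open. The HLA count cannot decide it, because it mixes HLA type with level. MHC class II genes were higher in Raji as a list, with medians of -1.19 for Namalwa minus Raji and 0.96 for Raji minus Ramos. A single RNA deposited under both names is not it, since 340 genes differed at least 2-fold, against at most 55 within a line, and PEG10 was at 2.37 in Namalwa but 9.35 in Ramos. Counted as 1 pair, the 2 lines left EZH2 at -0.50 (adjusted p = 0.199, range 0.0193 to 1.00 over alternatives) and 6 lists called.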
